A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

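DNase-seq maps accessible chromatin by sequencing DNA ends made by the endonuclease DNase I in intact nuclei. It was run here on 2 biological replicates of the budding yeast *Saccharomyces cerevisiae* strain W303, a common laboratory strain. Per the labels' protocols, an asynchronous culture in rich glucose medium at 37 °C was taken at an optical density of 0.7, unfixed nuclei were digested with DNase I for 16 min at 37 °C, and several enzyme amounts were tried. The amount used for each sequenced library is not given in the sources used here. Libraries were sequenced as single-end reads. Both samples belong to 1 group, so the only comparison between samples is of the replicates, and no difference between conditions was tested.

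The deposited files hold, per the file headers, the number of reads at each position of the 16 nuclear chromosomes and the mitochondrial genome, as raw counts on the forward strand, the reverse strand and both together. The 3 values agreed at every position, the total being the sum of both strands. Per the submitters' processing notes, Bowtie 0.12.7 and the build sacCer2 were used, and all coordinates are 1-based positions of that build. How reads matching several places were treated, and whether duplicate reads were removed, is not given in the sources used here. Positions with no read formed 424 runs of at least 300 bp, together 634260 bp or 5.25% of the nuclear genome. Of these, 176 lay within 20 kb of a chromosome end and 25 were 5000 to 6500 bp long, so low densities near ends also measure where reads were placed. The libraries were counted before any removal of repeated reads here. Intervals on shares cover counting error only and take each read as independent. Reads copied by PCR are not independent molecules, so the intervals may be too narrow even for that.

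The reference given with the data was a table of gene names and positions on another assembly, R64, so no gene annotation or sequence was laid over the positions. Of the planned results, 5 were therefore not run: promoter against coding region, promoter density of gene lists, feature classes, sequence preference of cuts and footprints at motifs. The rule fixed for names covered promoters of genes and the 10 strongest hypersensitive regions by the lower of the replicate densities, and only its second part was used. Regions named outside it were chosen after their values were seen. The gene lists and motifs fixed beforehand were not used here.

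The computations were made from the deposited counts with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9. The designs and most alternatives were fixed before the data were examined. A block of chromosome 12 (451438 to 489453, 38016 bp) was left out of the nuclear results, except the counts of runs without reads given above. It was defined after the data were seen, from long runs without reads around a very dense segment. It stands in for the ribosomal DNA array, which lies on this chromosome and which the design left out. Nuclear density is reads per bp relative to the nuclear mean of the same library.

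Replicates were compared in 76504 windows of 150 bp by Pearson and Spearman correlation across windows, which are not independent replicates. Each window's split of reads was tested against the nuclear totals by a two-sided exact binomial test (the smaller tail multiplied by 2) with Benjamini-Hochberg adjustment at 0.05. This test compares 2 libraries and takes counting error as the only noise. Hypersensitive regions were windows of 150 bp, moved in steps of 50 bp, whose count was at least 4 times the median window in both replicates, merged where they overlapped. No test was attached to them. Numbers of regions per chromosome were compared with the other chromosomes, and numbers near chromosome ends with the interior, by two-sided exact binomial tests on length outside runs of at least 100 bp without reads. These tests, values per chromosome end, windows of 10 kb and windows of 1 kb were added after the data were seen.

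For periodicity, the autocorrelation of counts on each strand was computed at lags of 1 to 250 bp as designed, with no limit on the count at a position. A sine wave was fitted to lags of 30 to 150 bp after removal of a polynomial of degree 4, over periods of 6 to 20 bp. These fit settings were chosen after the data were seen. Counts were also capped, as set beforehand, at the 99.9 percentile of positions with a read, 63 in replicate 1 and 41 in replicate 2. The planned profile around start codons was replaced, after the data were seen, by the mean profile around region centres, smoothed over 25 bp.

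The procedures were tested on simulated data. In the comparison of replicates with 76514 simulated windows, the window test recovered 92% of 100 windows changed by 1.5-fold and 100% of 100 windows changed by 2-fold, with 8 false calls. The simulated windows carried counting error only, and changes were planted in windows with at least 200 reads over both libraries. The real libraries differed by more than counting error, so the 8 false calls do not measure false calls there. The region procedure found 49 of 49 planted regions of 200 bp at 8-fold, with 0 elsewhere. Its simulated background was flat with counting error only, and 8-fold is far above the threshold of 4-fold. This outcome was therefore nearly fixed in advance. It checks that the procedure runs as written, not how it handles stacked reads or an uneven background. A planted period of 10.5 bp was found at 10.5 bp and explained 98.2% of the variance, while the best fit to flat simulated counts explained 4.76%. The planted signal was a cosine with counting error only and no stacked reads. Its recovery was therefore also nearly fixed in advance and does not show how the fit handles the real counts.

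Alternatives were window sizes, fold thresholds, capped counts, log counts, a count filter, a stricter threshold, a local background, other totals, smoothing and leaving out each replicate. Added after the data were seen were scaling by the median window ratio, leaving out 20 kb at chromosome ends, leaving out runs without reads, a limit of 10 counts per position, scaling of regions by nuclear totals, and periodicity outside hypersensitive regions.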

Results

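DNase I cuts were mapped across the genome of log-phase W303 yeast in 2 biological replicates of a single group. Replicate 1 held 45874761 reads and replicate 2 held 39014193. Of these, 43193273 and 37630460 lay on the 12032882 bp of nuclear chromosomes analysed, or 3.59 and 3.13 reads per bp with a median of 2 in both. No read began at 26.8% of these positions in replicate 1 and at 32.6% in replicate 2. Forward-strand reads made up 50.4% of each library. Positions with at least 100 reads numbered 4847 in replicate 1 and 704 in replicate 2 and held 2.25% and 0.576% of nuclear reads.

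To locate accessible chromatin, hypersensitive regions were defined as places where both replicates reached at least 4 times the median window. There were 2613 such regions on the 16 nuclear chromosomes. They covered 749650 bp, or 6.23% of the nuclear genome analysed, and held 26.1% ± 2.71 (SD, n = 2) of nuclear reads. The share was 28.1% in replicate 1 (95% Wilson interval 28.05 to 28.08%) and 24.2% in replicate 2 (24.21 to 24.24%). Read density inside the regions was 5.87 times that outside in replicate 1 and 4.81 times in replicate 2. The regions had a median width of 250 bp (interquartile range 200 to 300) and a median distance between neighbours of 3100 bp (1650 to 5775). In both replicates 59 regions reached 10-fold and 3 reached 20-fold.

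Among the 10 strongest regions by the lower replicate, 5 lay more than 100 kb from a chromosome end, outside the neighbourhood of the block left out of chromosome 12. Chromosome 7 at 428051 to 428600 reached 17.6-fold and 16.0-fold over the median window in replicates 1 and 2. Chromosome 10 at 402451 to 402850 reached 14.6-fold and 14.4-fold, and chromosome 4 at 1135401 to 1135750 reached 17.7-fold and 14.2-fold. Chromosome 10 at 632951 to 633550 reached 17.3-fold and 13.9-fold, and chromosome 1 at 119601 to 119950 reached 18.4-fold and 13.2-fold. The forward strand held 53.4% and 53.5% of reads in the chromosome 7 region and 48.1% and 47.8% in the first chromosome 10 region. It held 65.8% and 58.8% in the chromosome 4 region, 75.3% and 69.2% in the second chromosome 10 region and 32.5% and 44.1% in the chromosome 1 region. Gene annotation of this build was not used here, so the regions are given by position.

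**Figure D1:**
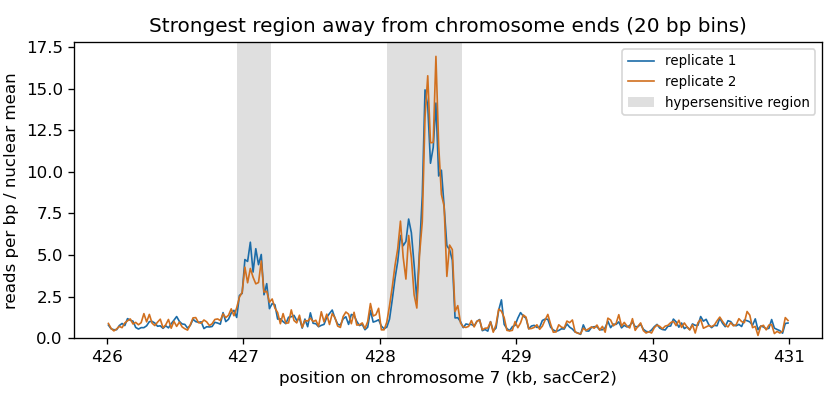
Read density in 20 bp bins (vertical axis, reads per bp relative to the nuclear mean) along 426001 to 431000 of chromosome 7 (horizontal axis, kb), with a line per replicate and hypersensitive regions shaded. The lines of both replicates rise together in the region at 428051 to 428600, which reached 17.6-fold and 16.0-fold over the median window.

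The other 5 strongest regions lay near chromosome ends or beside the block left out. Chromosome 4 at 1525251 to 1525550, 6369 bp from its end, reached 193-fold in replicate 1 and 49.2-fold in replicate 2, with 1.03% and 0.883% of reads on the forward strand. A single position held 33.7% and 29.03% of its reads. Chromosome 14 at 784101 to 784300, 33 bp from its end, reached 120-fold and 26.3-fold with 0.521% and 0.545% forward reads. Chromosome 8 at 556801 to 557100 reached 117-fold and 22.6-fold with 8.04% and 6.98% forward reads. Chromosome 3 at 1 to 400 reached 55.3-fold and 14.7-fold with 99.65% and 99.67% forward reads. Chromosome 12 at 490501 to 490900, beside the block left out, reached 35.1-fold and 13.7-fold with 14.7% and 40.5% forward reads.

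The widest region was 1650 bp at 369851 to 371500 of chromosome 12, with peaks of 18.5-fold and 9.35-fold. It was followed by 1550 bp at 138101 to 139650 of chromosome 9, with 9.64-fold and 8.60-fold. The longest stretch between neighbouring regions, among stretches with at least 80% of positions outside runs without reads, was 38.55 kb on chromosome 4 (769501 to 808050). Its density outside those runs was 0.745 ± 0.011 (SD, n = 2) times the nuclear mean.

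Regions were spread over all 16 chromosomes. Chromosome 5 carried 30.6 per 100 kb against 22.6 on the others, outside runs without reads, and was the only chromosome past the threshold (two-sided exact binomial test, adjusted p = 0.0051 over 16 chromosomes). Regions were called against 1 genome-wide median, and the median 150 bp window of chromosome 5 was 1.09 and 1.08 times the nuclear median in replicates 1 and 2. Whether its excess of regions holds against a local background was not tested. Chromosome 1 carried 19.4 against 23.1 (exact binomial adjusted p = 0.926). In the terminal 1 kb there were 5 regions in 9.43 kb, or 53.0 per 100 kb (exact binomial adjusted p = 0.187). Between 1 and 5 kb from chromosome ends the density was 2.83 per 100 kb, resting on 1 region in 35.4 kb, against 23.8 beyond 100 kb (exact binomial adjusted p = 0.0252 over 6 bins). It was 18.0 at 5 to 10 kb (exact binomial adjusted p = 0.356), and 16.9 at 10 to 20 kb and 20.0 at 20 to 50 kb (exact binomial adjusted p = 0.0675 for each). The tests take regions as independent of each other. Regions along a chromosome are not, so these p-values may be too small.

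The replicates shared most of the length of their accessible regions. Called alone, replicate 1 gave 3160 regions and replicate 2 gave 2710. Regions of replicate 2 lay within those of replicate 1 over 96.0% of their length, and those of replicate 1 within replicate 2 over 73.9%. The shared length was 11.4 times that of independent sets. The log2 fold over background correlated at r = 0.717 across regions. Only regions that reached 4-fold in both replicates enter this value, so it does not cover regions found in 1 replicate. Relative to the median window, 2078 of the 2613 regions were stronger in replicate 1 (median log2 ratio 0.16), but relative to nuclear totals only 1203 were (median -0.02), so the direction depends on the scaling.

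Across 150 bp windows the counts correlated at r = 0.855 and rho = 0.906. The exact binomial test called 40492 windows (52.9%) as differing at an adjusted p under 0.05, and 44632 at an unadjusted p under 0.05. Of the called windows 9944 were higher in replicate 1 and 30548 in replicate 2, a share of 24.6% higher in replicate 1. With scaling by the median window ratio the call count was 25015 (32.7%) and the split turned, with 16209 higher in replicate 1 and 8806 in replicate 2, or 64.8% higher in replicate 1. The median log2 ratio of replicate 1 to replicate 2 under total scaling was -0.18. Differences of more than 2-fold were mostly in 1 direction, with 1187 windows higher in replicate 1 and 71 in replicate 2. The SD of the log2 ratio was 0.36, against 0.14 from counting error. By decile of window count, the median log2 ratio was -0.23 in the lowest and 0.01 in the highest decile. The windows thus differed between libraries by more than counting error, and with n = 2 no window was tested against biological spread.

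At the helical scale, the designed fit without a limit on counts gave no shared period. The best periods were 7.7 bp in replicate 1 and 16.3 bp in replicate 2, a mean of 12 ± 6.08 bp (SD, n = 2), and explained 5.84% and 6.34% of the variance. With counts capped at 63 and 41 reads per strand position, both replicates gave 10.45 bp, which explained 59.3% and 62.3%. This period appeared only where high counts at single positions were limited. Outside hypersensitive regions the capped periods were 10.4 and 10.35 bp. On the mitochondrial genome, which has no nucleosomes, the capped fits gave 8.4 and 20 bp and explained 5.33% and 8.07%. In 132 nuclear segments of the same length, 85779 bp, the median was 11.8% in replicate 1 and 13.5% in replicate 2, and 61 and 91 segments gave a period within 1 bp of 10.45 bp, so at this length a nuclear segment also often missed it. Of the 132 segments, 4 and 12 lay at or below the mitochondrial value, so the nuclear and mitochondrial values overlapped at this length. With the mitochondrial cap scaled to its density (241 and 100 reads), its fits explained 5.13% and 5.72%, and 4 segments lay at or below it in each replicate. Periods under 6 bp were not fitted. The mitochondrial autocorrelation peaked at lags of 75, 78 and 81 bp in both replicates, steps shorter than that. A low explained share therefore does not show that the mitochondrial signal had no period.

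**Figure D2:**
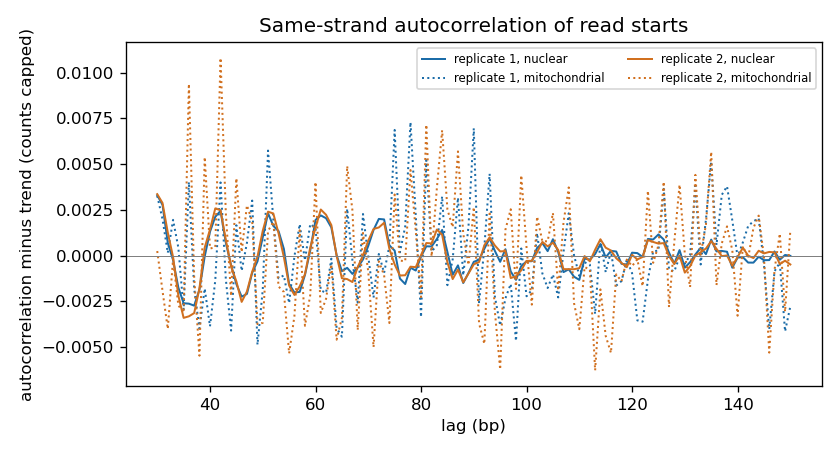
Autocorrelation of read starts on the same strand after removal of the trend (vertical axis, no unit, counts capped at 63 and 41) against lag (horizontal axis, bp), for nuclear chromosomes (solid) and the mitochondrial genome (dotted) in each replicate. The nuclear lines of both replicates recur every 10.45 bp. The mitochondrial lines also rise and fall, with peaks at lags of 75, 78 and 81 bp in both replicates. Such steps are shorter than the shortest period fitted, 6 bp.

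Around 2555 regions at more than 20 kb from chromosome ends, density at the centre was 5.04 ± 0.43 (SD, n = 2) times the nuclear mean. Within 30 bp it first rose, from 5.34 to 5.39 in replicate 1 and from 4.73 to 4.86 in replicate 2. Further out it fell and showed repeated maxima on the flanks. The first flanking maximum lay at 224.5 ± 2.1 bp and the second at 400.5 ± 3.5 bp from the centre, a spacing of 176 ± 1.4 bp. The minima lay at 167.5 ± 3.5 and 335 ± 1.4 bp, a spacing of 167.5 ± 2.1 bp. The spacing thus depended on which features were used by more than the SD between replicates. Density was 1.63 ± 0.095 at the first minimum and 1.83 ± 0.12 at the first maximum, both located by search in the same profile. Centres were picked for their height, which sets the central peak. When regions called in replicate 1 alone were profiled in replicate 2, the maxima lay at 225 and 403 bp, and in the opposite arrangement at 223 and 404 bp.

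**Figure D3:**
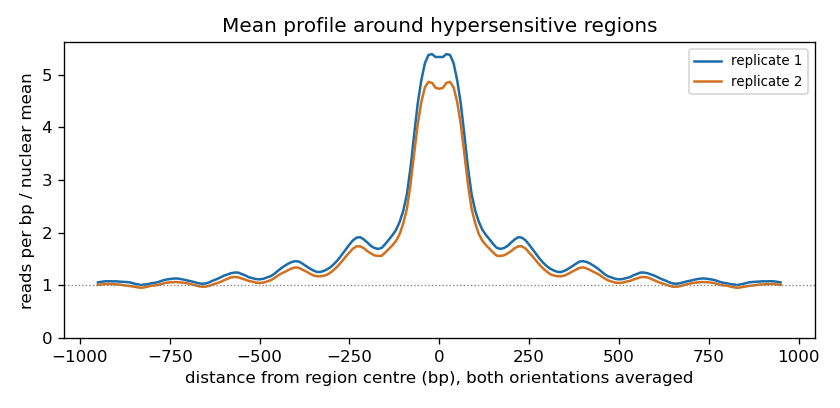
Mean read density (vertical axis, relative to the nuclear mean) against distance from the centre of 2555 hypersensitive regions (horizontal axis, bp), smoothed over 25 bp with both orientations averaged, with a line per replicate. The first flanking maxima lie at 223 bp in replicate 1 and 226 bp in replicate 2.

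Chromosomes differed little in read density. Chromosome 5 had the highest mean, 1.126 ± 0.017 (SD, n = 2) times the nuclear mean, and chromosome 8 the lowest, 0.899 ± 0.035. Chromosome 6 had 1.18 in replicate 1 and 0.987 in replicate 2, and chromosome 1 had 1.00 and 0.858. In replicate 1 alone the highest was chromosome 6, and in replicate 2 alone the lowest was chromosome 1. The mean of chromosome 1, 0.931, rose to 1.06 with runs without reads left out. Without 20 kb at chromosome ends it was 1.05. The mitochondrial genome had 3.14 ± 0.98 (SD, n = 2) times the nuclear density. It took 2.57% of reads in replicate 1 (95% Wilson interval 2.568 to 2.577%) and 1.68% in replicate 2 (1.675 to 1.683%).

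**Figure D4:**
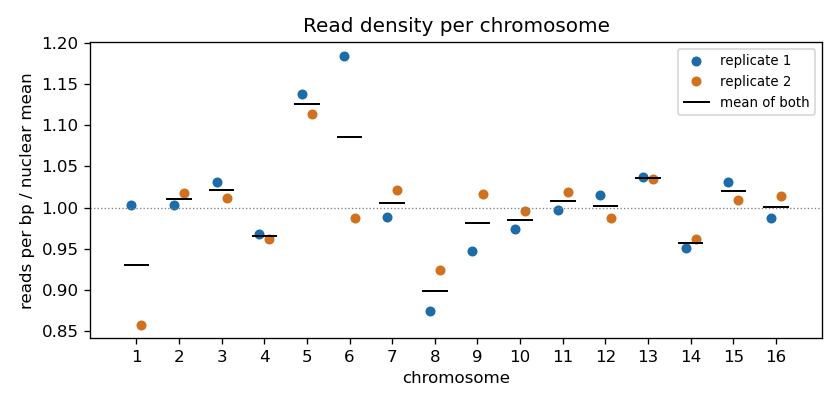
Read density of each nuclear chromosome relative to the nuclear mean (vertical axis, ratio) by chromosome number (horizontal axis), with a point per replicate and a bar at their mean. Chromosome 5 is above 1 and chromosome 8 below 1 in both replicates, while the replicates of chromosomes 1 and 6 lie apart.

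By distance from chromosome ends, median density outside runs without reads was 1.38 ± 0.46 (SD, n = 2) in the terminal 1 kb over 13 ends, with 1.70 in replicate 1 and 1.05 in replicate 2. It was 0.585 ± 0.20 at 1 to 5 kb over 10 ends, 0.938 ± 0.15 at 5 to 10 kb over 22 ends and 0.889 ± 0.029 at 10 to 20 kb over 27 ends. It was 0.963 ± 0.071 at 20 to 50 kb and 1.00 ± 0.031 at 50 to 100 kb, each over 32 ends. In the terminal 1 kb, 93.3% of reads in replicate 1 and 95.2% in replicate 2 lay on the strand that reads away from the end, against 50.5% and 50.1% at 50 to 100 kb. Together, the ends of chromosomes 14 (right) and 3 (left) held 46.6% of these reads in replicate 1 and 44.7% in replicate 2. Without these 2 ends, the shares on the strand that reads away from the end were 88.1% and 91.8%. Of the ends with at least 100 reads, the share was above 50% at 16 of 21 in replicate 1 and at 18 of 19 in replicate 2, and the lowest were 4.05% and 23.9%. It was 36.7% and 52.2% at 1 to 5 kb, 49.1% and 49.1% at 5 to 10 kb, and 44.1% and 45.0% at 10 to 20 kb. The terminal kilobases held 151049 reads in replicate 1 and 38519 in replicate 2.

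Over 1093 windows of 10 kb with at least 80% of positions outside runs of at least 100 bp without reads, density over those positions ranged from 0.677 at the 5th percentile to 1.64 at the 95th, and the replicates correlated at rho = 0.902 and r = 0.777 across windows. Ranked by the lower replicate, the highest window, at 220001 to 230000 of chromosome 6, had 5.62 and 2.00. The window at 320001 to 330000 of chromosome 11 had 1.98 and 1.99. Ranked by the higher replicate, the lowest window, at 90001 to 100000 of chromosome 1, had 0.343 and 0.407 and held no hypersensitive region. Next in that order were 270001 to 280000 of chromosome 5, with 0.390 and 0.436, and 200001 to 210000 of chromosome 8, with 0.435 and 0.457. By the mean of both replicates, 1 to 10000 of chromosome 1 (0.429) and 1370001 to 1380000 of chromosome 4 (0.432) were below the chromosome 8 window (0.446).

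**Figure D5:**
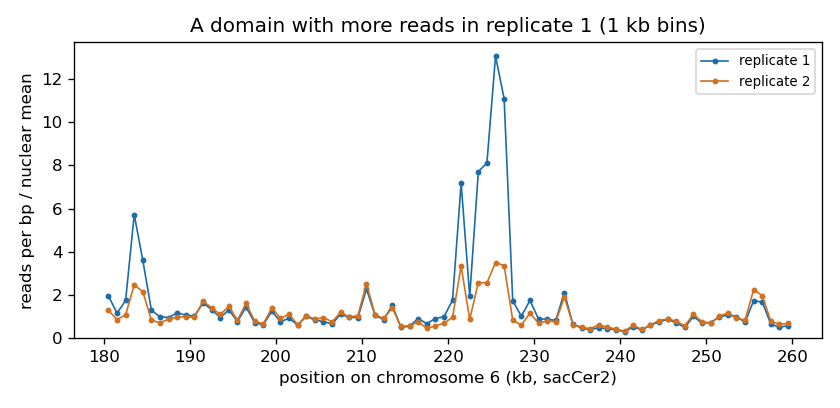
Read density in 1 kb bins (vertical axis, relative to the nuclear mean) along part of chromosome 6 (horizontal axis, kb), with a line per replicate. All positions of a bin are counted. The highest bin reaches 13.1 in replicate 1 and 3.50 in replicate 2.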

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

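A segment in the block left out of chromosome 12 was picked out because it carried many reads in data outside the comparisons. The 794 bp at 459781 to 460574 held 1501254 reads in replicate 1, or 3.27% of the library (95% Wilson interval 3.267 to 3.278%). In replicate 2 it held 728792 reads, or 1.87% (1.864 to 1.872%). Its density was 527 times the nuclear mean in replicate 1 and 294 times in replicate 2, and outside it only 2 positions of the block had a read.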

How the results depend on the processing

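Scaling by the median window ratio, leaving out 20 kb at chromosome ends or runs without reads, the limit of 10 counts, scaling regions by nuclear totals, and periods outside regions were chosen after seeing the data. The correlation of replicates was 0.816 in 50 bp and 0.842 in 1000 bp windows, 0.908 with capped counts, 0.940 on log counts, 0.884 without chromosome ends and 0.877 without runs lacking reads. The share of windows called was 27.1% at 50 bp, 85.6% at 1000 bp and 32.7% under median scaling. The share of called windows higher in replicate 1 was 34.2% at 50 bp, 20.8% at 1000 bp, 26.2% with capped counts, 27.9% at a threshold of 0.01 and 64.8% under median scaling. The number of regions was 950 at 6-fold and 1426 in 250 bp windows. It stayed within 1.5 times 2613 under the other 8 settings, but rose to 3884 at 3-fold, near that bound, and to 3407 in 100 bp windows. With a replicate left out it was 2710 to 3160. The regions stronger in replicate 1 were 2078 relative to the median window and 1203 of 2613 relative to nuclear totals, a reversed majority. The share of reads in regions was 34.1% at 3-fold, 12.2% at 6-fold and 22.0% in 250 bp windows, and 24.9 to 34.0% with a replicate left out. The period of 12 bp is a mean of unlike values, 7.7 to 16.3 bp with a replicate left out. It was 10.45 bp with capped counts and 10.4 bp with the limit of 10 or outside regions. The spacing of flanking maxima was 167.5 bp with 11 bp smoothing and 173 bp with the limit of 10, and 175 to 177 bp with a replicate left out. Chromosome 5 had 1.08 with all reads as the total. Chromosome 8 moved by less than the replicate SD under its 6 alternatives. These include leaving out each replicate, which with n = 2 cannot move the mean by more than the SD. The cause of these changes was not tested, apart from thresholds and windows, which set what is counted. The alternative leaving out repeated 20-mers and all alternatives of the 5 designs not run were not run. Depth limits the 50 bp windows most, with medians of 123 and 121 reads.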

Other observations

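The windows, domains and limits used here were set after the data were seen. The replicates differed in domains. Counts were capped at 63 and 41 per strand position, and log ratios were centred on their median. Of 11171 windows of 1 kb with over 200 reads, 429 had a log2 ratio of replicate 1 to replicate 2 more than 0.8 above the median and 0 lay as far below it. They formed 106 domains on 16 chromosomes, 70 of at least 3 kb and some a single window of 1 kb. Inside lay 190 of the 2613 hypersensitive regions. Whether that is more than the length or read density of the domains would give was not tested. The log2 ratios of examples are over their windows past the limit, on capped counts. Examples are 11 kb at 218001 to 229000 of chromosome 6 (log2 ratio 1.51), 10 kb at 404001 to 414000 of chromosome 13 (1.50) and 11 kb at 424001 to 435000 of chromosome 4 (1.07). The log ratio correlated with itself at 0.86 over 1 kb, 0.51 over 5 kb and -0.01 over 20 kb.

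Stacked reads at single positions were examined as a candidate explanation, although the windows had been found on counts already capped per strand position. The 20% of strand positions with the most reads in each window were removed from the uncapped counts. After that, 37.3% of the windows stayed over the limit, between the bounds set in advance. Such removal can lower the ratio of windows picked for a high ratio whatever the cause. The value therefore does not show that stacked reads contribute. A candidate explanation in which recovery of a cut depends on cuts nearby predicted a partial correlation of the log ratio with density 1 to 5 kb away. It was 0.19, also between its bounds, and -0.04 at 20 to 24 kb. Both stay open, and no biological explanation was tested, since the design has 1 group.

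Counts on the forward strand, limited to 10 per position, correlated with reverse-strand counts 20 bp downstream more than at nearby lags. The excess was 0.066 in replicate 1 and 0.048 in replicate 2 on nuclear chromosomes, and 0.173 and 0.084 on the mitochondrial genome. A candidate explanation is the tag length of the library, which would act on any DNA. The lower ratio of mitochondrial to nuclear excess was 1.74, above the bound set before the result was seen, as this explanation predicts. Any other cause that acts on all DNA predicts the same, so the ratio does not single out tag length. No biological explanation was tested.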
